A study of Homo sapiens with 3 samples.

How the data were processed

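Per the labels' protocols, total RNA was isolated with TRIzol from HEK293T cells and derivatives of them, libraries were made with a Collibri 3' mRNA kit, which captures the 3' ends of polyadenylated transcripts, and sequencing was paired-end. The 3 samples analysed were 1 library each of WT, DGCR8-KO and DGCR8-E518K cells, as the labels name them. How the edits were made, the number of clones, and culture and sequencing batches were not given in the sources used here.

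The submitters' processing notes name cutadapt, STAR 2.7.11a, bedtools and the genome build GRCh38. The gene annotation and the counting rule were not given in the sources used here. The deposited table gave 19439 genes, and its values (unit: signal) were read counts that the authors had divided by the GAPDH count of the same library, so that GAPDH equalled 1 in each column. The scaling was checked on the values: in each library 100% of them were whole multiples of 1 over a single number, within 1e-06 reads, which recovered 13864 GAPDH reads in WT, 1448 in DGCR8-KO and 1095 in DGCR8-E518K. The lowest value in each column was 1 read. Whether 1 was put in for 0 or added to each gene was not given in the sources used here, so a gene at this floor may have had 0 reads. Its ratio and interval treat the floor as 1 read. With 0 reads the far end of the interval would not be finite. The table held 0 columns of other samples.

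Summed over the table, WT had 16399696 reads, DGCR8-KO 1040117 and DGCR8-E518K 1370296. Of the genes, 2010, 6493 and 5588 stood at the floor in that order. GAPDH stood at 845, 1392 and 799 CPM, and the 10 most abundant genes of each library took 7.77%, 5.32% and 6.32% of its reads. Reads carried no molecular identifier in the table, so intervals cover counting error only.

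For each of 3 comparisons, the log2 fold was computed from the deposited values after a pseudocount was added, and the median log2 fold of the analysed genes was subtracted so that GAPDH did not set the direction. The analysed genes were the 10000 of highest mean over the libraries. The pseudocount was the median of those means divided by 10, that is 3.85 per 1000 GAPDH reads, or 53.4 reads in WT, 5.57 in DGCR8-KO and 4.21 in DGCR8-E518K. A gene was counted as higher or lower at 2-fold on this scale. Ratios printed for single genes are ratios of reads without a pseudocount, relative to the median gene, with exact Clopper-Pearson 95% intervals, and levels have exact Poisson 95% intervals. With 1 library per group no count test was possible. Genes named were DGCR8, DROSHA and GAPDH, and by log2 fold the 10 highest and 10 lowest of each comparison with WT. For DGCR8-E518K vs DGCR8-KO the 5 highest and 5 lowest were named. A list outside the range of random lists gave up to 4 members furthest in its own direction. Any other list gave its 2 highest and 2 lowest members. Of the items that this rule would name, 1 is not reported here.

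Gene lists were written from general knowledge before the data were examined, as were the seed families, the comparisons, the naming rule and most alternatives. Of 36 lists, 31 had at least 8 analysed members. The 5 left out were mitochondrially encoded mRNAs (0 in the table), replication-dependent histones (3 analysed) and markers of blood (0), fibroblasts and endothelium (1) and liver and gut lines (1). The median log2 fold of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and called outside below percentile 2.5 or above 97.5. If genes varied independently, 1.55 of 31 lists would lie outside in a comparison by chance. Genes that vary together between cultures could put more lists outside. Percentiles describe these libraries and are not tests across samples. The target lists rest on memory of published targets, and the alias IMP3 in the let-7 list names another gene and was kept.

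Each microRNA family was given by its 7-base word (seed bases 2 to 8), and its site was the reverse complement of the word followed by A, 8 bases in all. Sites were sought in the 3' UTR of 1 transcript per gene from GENCODE 29, to which 19403 of the 19439 symbols were matched, 15245 of them with an annotated 3' UTR. A linear trend on log 3' UTR length, 3' UTR base composition and log mean level was removed, and the mean log2 fold of the genes with a site was ranked among all words with at least 50 genes (12576 of 16384). Of 20 families that depend on Microprocessor, 19 could be ranked, beside 2 that bypass it and 8 not known from kidney lines.

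Correlation and overlap of the comparisons with WT were set beside 20 simulations of unchanged libraries at the real depths that shared 1 WT library, with counting error alone or with added noise. For the shared changes the WT reads were also split at random, gene by gene, into a part for each comparison, and results were averaged over 20 splits; this step was chosen after the data had been seen. The pipeline was tested on simulated data: of genes changed 4-fold between WT and DGCR8-KO, 95.7% were recovered at 2-fold, a list shifted by 0.5 stood at percentile 100, 4 of 90 unshifted lists lay outside, and a family raised by 0.3 topped all words. Alternatives tried were the deposited GAPDH scale without centring, scaling to library totals, a trimmed mean, pseudocounts of the median divided by 100 and by 2, 5000 genes, no filter on low values, list means, random lists without matching, 7-base and 6-base sites, no trend removal and the longest 3' UTR. The GAPDH scale without centring and the trimmed mean shift all genes alike. They cannot move the percentile of a list, and tallies of list positions over the alternatives include them. Thinning to the DGCR8-KO depth, a trend on transcript length, base composition and expression, weighting words by the number of genes, and host lists of all genes with a microRNA in the annotation were added after the data had been seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Other data of the study were not used here.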

Results

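The series measured messenger RNA in HEK293T cells, a widely used human line derived from embryonic kidney, and in derivatives of that line edited at DGCR8. DGCR8 is the RNA-binding partner of the nuclease DROSHA in Microprocessor, the nuclear complex that cuts hairpins out of primary microRNA transcripts. The series title sets the question, which is how Microprocessor mutations found in Wilms tumor, a childhood kidney tumor, act. The 3 samples were 1 library each of unedited cells (WT), cells labelled as a DGCR8 knockout (DGCR8-KO) and cells labelled with the DGCR8 substitution E518K (DGCR8-E518K). The deposited values gave 16399696 reads for WT, 1040117 for DGCR8-KO and 1370296 for DGCR8-E518K. A gene of the 10000 analysed had a median of 547, 42 and 49 reads in that order. There were no replicates, so no difference below has a replicate check or a p-value, and the 95% intervals cover counting error only. Ratios of reads are relative to the median gene unless GAPDH is named, and genes were ordered by a log2 fold with a pseudocount, which tempers ratios at low reads.

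DGCR8 (chromosome 22, 20080232 to 20111877, plus strand, GRCh38) was higher in both edited libraries than in WT. It had 16.5 reads per 1000 GAPDH reads in WT (exact Poisson interval 14.4 to 18.8), 55.2 (43.8 to 68.8) in DGCR8-KO and 100.5 (82.6 to 121) in DGCR8-E518K. Relative to the median gene it stood at 4.49 times the WT level (3.43 to 5.81) in DGCR8-KO and 5.32 times (4.20 to 6.70) in DGCR8-E518K. The annotation places the microRNA genes MIR1306 and MIR3618 in exons of DGCR8. A library of 3' ends reads the transcript far from most coding edits, so these levels do not check the edit that either label names. DROSHA had 72.1 reads per 1000 GAPDH reads (67.7 to 76.7) in WT, 76.7 (63.1 to 92.3) in DGCR8-KO and 110.5 (91.7 to 132) in DGCR8-E518K. On the scale of library totals (CPM), DGCR8 stood at 14 (12.2 to 15.9), 76.9 (61.0 to 95.7) and 80.3 (66.0 to 96.8). DROSHA stood at 61.0 (57.3 to 64.9), 106.7 (87.8 to 128.5) and 88.3 (73.3 to 105.5) CPM. Its level in DGCR8-KO relative to the other libraries thus depended on the scale. The 30 analysed neighbours of DGCR8 in band 22q11.21 had median log2 folds of 0.03 in DGCR8-KO and 0.06 in DGCR8-E518K, at percentiles 62.1 and 73.1 of matched random lists.

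**Figure D1:**
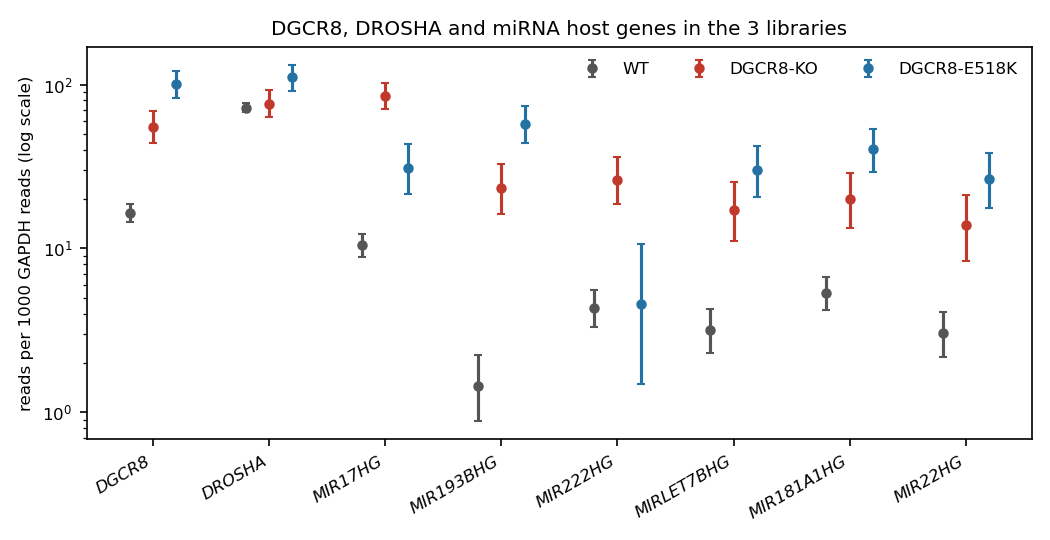
Reads per 1000 GAPDH reads (log scale) of DGCR8, DROSHA and 6 genes that host microRNAs in the WT, DGCR8-KO and DGCR8-E518K libraries, 1 library each. Bars are exact Poisson 95% intervals, which cover counting error only; DGCR8 stands at 16.5, 55.2 and 100.5 in that order, and MIR17HG at 10.5, 85.6 and 31.1.

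The comparison of DGCR8-KO with WT asks which transcripts differ in the cells labelled as a knockout. The gene furthest above WT was GPC5 (chromosome 13, 91398607 to 92873682), a cell-surface proteoglycan of the glypican family, at 37.8 times the WT level (29 to 49.9, 221 reads against 75). PRTG, an immunoglobulin-family membrane receptor, stood at 18.7 times (14.9 to 23.6) and the lysosomal protein CTSA at 16.8 times (13.3 to 21.3). INSIG1, which restrains cholesterol synthesis in the endoplasmic reticulum, stood at 13.8 times (11.4 to 16.8) and MIR17HG (chromosome 13, 91347820 to 91354579), the primary transcript of the miR-17 cluster, at 11 times (8.57 to 14.1). Furthest below WT was NUPR1 (chromosome 16, 28532708 to 28539174), a stress-induced transcriptional regulator, listed at the file's floor of 1 read in DGCR8-KO against 3713 reads in WT, which is 289 times lower (51.9 to 11424). GDF15, a secreted stress cytokine, was also at the floor of 1 read against 2285 in WT, or 178 times lower (31.9 to 7032).

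The other genes among the 10 highest in DGCR8-KO were ENPP5 (29.6 times, 17.8 to 50.6), HSP90AA2P (19), HOXB5 (16.1), PBXIP1 (13.4) and the stress ligand MICA (12.8). HSP90AA2P is a processed pseudogene close to HSP90AA1, which itself stood at 2.47 times WT, and reads could be split between such copies. The remaining 8 of the 10 lowest were INHBE, a subunit of secreted inhibins and activins (31.4 times lower, 19.3 to 54.9), GAS5 (20.9), ZFAS1 (17.6), CLVS1 (15.7), PHF21B (24.2), TMEM14C (24.1), LINC01980 (31.1) and S100P at the floor of 1 read (82.5, 14.8 to 3260). In all, 1078 genes were at least 2-fold higher and 1220 at least 2-fold lower, and 105 and 200 passed 4-fold. The counting interval of every one of these 2-fold ratios excluded 1. Unchanged libraries simulated with counting error alone put 8 genes past 2-fold. Spread between cultures, clones or preparations has no measure here; with noise as wide as the folds of DGCR8-E518K added, they put 195 genes higher and 266 lower. The split between higher and lower depends on the scale. The median log2 fold on the deposited GAPDH scale was -0.42, where 414 genes were higher and 2444 lower (14.5% higher against 46.9%), and with each library scaled to its total 1636 were higher and 924 lower (63.9%).

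The long noncoding genes listed in advance as microRNA hosts were higher as a group in DGCR8-KO. The rule by which reads were assigned to genes is not given in the sources used here, so counts of host genes could include reads from introns or beside hairpins. Of 18 analysed, 9 were at least 2-fold higher and 0 lower, with a median log2 fold of 0.86 at percentile 99.95 of random lists matched on expression. Examples are MIR17HG, MIR193BHG, which carries miR-193b and miR-365a, at 21.8 times WT (12.2 to 40.0), MIR222HG at 8.13 times (5.27 to 12.4) and MIRLET7BHG, a let-7 host, at 7.30 times (4.28 to 12.2). The protein-coding hosts listed in advance had a median of 0.07 (percentile 79.8), with 0 of 29 higher and 3 lower, among them COPZ1, the host of miR-148b, 2.16 times lower (1.90 to 2.47). Without a filter on low values the percentile of the listed noncoding hosts was 86.4. The medians of annotated hosts as a whole did not show this rise, in a check chosen after the data had been seen. The annotated microRNAs were not filtered for processing by Microprocessor or for expression in these cells. All 27 analysed long noncoding genes with an annotated microRNA, 15 of them in the list, had a median of 0.25 inside the range of random lists (percentile 80.9, 9 higher, 1 lower), and the 12 outside the list one of -0.24 (0 higher). The 622 annotated protein-coding hosts had a median of 0.02 (percentile 71.7, 74 higher, 59 lower).

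Targets of the miR-17 and miR-106b families were higher in DGCR8-KO, with 14 of 39 analysed at least 2-fold higher, 0 lower, and a median log2 fold of 0.54 (percentile 99.96). They include ENPP5, CROT, a peroxisomal carnitine acyltransferase, at 9.17 times (5.54 to 15), the pro-apoptotic BCL2L11 at 5.37 times (3.86 to 7.38) and the transcriptional repressor ZBTB4 at 4.25 times (3.32 to 5.4). Among the 5000 genes of highest mean the percentile of this list was 91.6. The medians of 6 other target lists were inside the range of random lists: miR-25 and miR-92 at 0.41 (percentile 94.5, 7 of 23 higher), miR-21 at 0.32 (96.3, 4 of 25), miR-15 and miR-16 at 0.25 (95.8, 10 of 40), let-7 at 0.13 (91.1, 7 of 39), miR-10 and miR-100 at 0.13 (75.3, 3 of 24) and miR-30 at -0.01 (50.2, 4 of 26). Within the let-7 list NR6A1 stood at 4.10 times WT and NRAS was 5.45 times lower. The control lists for microRNAs with no known expression in kidney lines, miR-122 and miR-124, had medians of -0.18 and 0.18 (percentiles 27.0 and 93.8).

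Seed sites were then ranked against all other words of the same length. Across 9464 genes with an annotated 3' UTR, 12576 words had sites in at least 50 genes, and 5 of 19 Microprocessor-dependent families lay among the top 5% of words by mean log2 fold in DGCR8-KO. The miR-18 site (GCACCTTA, 171 genes) had a mean of 0.27, which 0.0716% of words exceeded, and the miR-17 family site (GCACTTTA, 502 genes) a mean of 0.25, exceeded by 0.0954%. The miR-25/32/92 site (GTGCAATA, 333 genes) had a mean of 0.19, the miR-19 site (TTTGCACA, 664 genes) 0.14 and the miR-148 family site (TGCACTGA, 442 genes) 0.12, exceeded by 0.310%, 1.12% and 1.63% of words. The first 4 of these families are the microRNAs made from MIR17HG and its relatives. The let-7 site (CTACCTCA, 362 genes) had a mean of -0.03, exceeded by 68.9% of words. Of the families that bypass Microprocessor, miR-320 and miR-484, 0 of 2 were in the top 5%, as were 0 of 8 control families. The rank of miR-17 and miR-18 needed the full site. With 7-base sites their means were 0.06 and 0.04, exceeded by 5.49% and 9.0% of words, and with 6-base sites 10.5% and 18.6% of words exceeded them. Of the 5 families only miR-19 and miR-25/32/92 were in the top 5% at both shorter lengths, 2 of 5, joined by the miR-130 family with 7-base sites and by 2 families with 6-base sites.

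**Figure D2:**
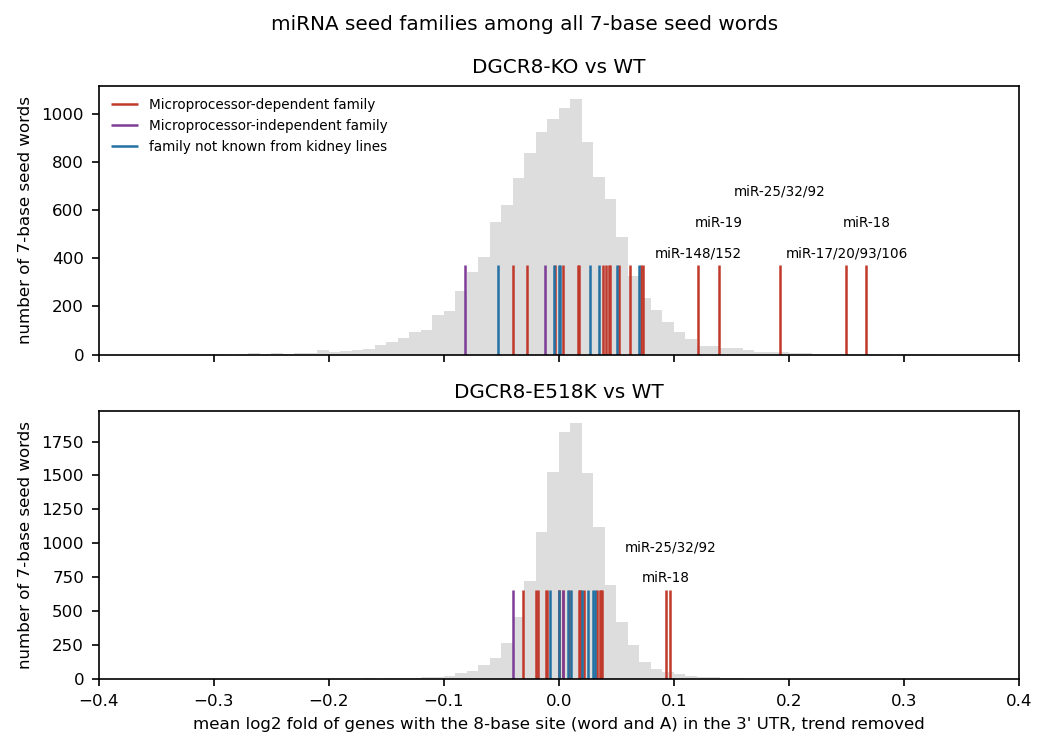
Histogram of the mean log2 fold of genes with each 8-base site in the 3' UTR, over all 12576 words, in DGCR8-KO vs WT (top) and DGCR8-E518K vs WT (bottom), after removal of a trend on 3' UTR length, base composition and expression. Vertical lines mark microRNA families; miR-18 at 0.27 and the miR-17 family at 0.25 lie at the right edge in DGCR8-KO.

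HOX genes, which set positional identity, formed the highest of the 31 lists in DGCR8-KO, with a median log2 fold of 1.12 (percentile 100), 15 of 26 at least 2-fold higher and 0 lower. HOXB5 stood at 16.1 times WT (12.2 to 21.4), HOXB6 at 9.03 times (7.54 to 10.8), HOXB8 at 7.87 times (5.56 to 11.1) and HOXC8 at 4.86 times (3.94 to 5.95). Cholesterol synthesis genes had a median of 0.67 (percentile 99.98), with 6 of 22 higher and 1 lower; beside INSIG1 these include the sterol oxidase MSMO1 (8.23 times, 6.91 to 9.79) and SQLE (3.83, 3.09 to 4.71). Nephron progenitor and Wilms tumor genes had a median of 0.38 (percentile 99.7, 9 of 33 higher, 1 lower), among them HOXA10 (4.57 times), the microRNA-processing nuclease gene DICER1 (4.34), HOXA11 (3.02) and BCOR (2.81). HOXA10 and HOXA11 are HOX genes as well, and the median without them was not computed. Mitosis genes had a median of 0.35 (percentile 99.8), although only 4 of 40 were 2-fold higher and 3 lower; KIF23, a kinesin of cytokinesis, stood at 3.91 times and ASPM at 2.48 times. Glycolysis and hypoxia genes had a median of 0.38 (percentile 99.7) with 3 of 31 higher, including NDRG1 at 3.43 times (3.10 to 3.78), and 3 lower. Epithelial genes had a median of 0.81 (percentile 98.99, 4 of 9 higher, 1 lower), among them the tight-junction genes OCLN (2.34) and TJP1 (2.23); this position was lost under 4 of 10 alternatives. Housekeeping reference genes had a median of 0.24 (percentile 99.9, 3 of 29 higher, 4 lower), with B2M at 4.29 times; without matching on expression the percentile was 90.4. On the uncentred GAPDH scale the medians of the nephron, mitosis, glycolysis and housekeeping lists turned negative, while HOX and cholesterol genes stayed above 0.

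Genes that host small nucleolar RNAs in their introns were the lowest list in DGCR8-KO, with a median log2 fold of -1.45 (percentile 0), 17 of 24 at least 2-fold lower and 0 higher. GAS5 was 20.9 times lower (16.9 to 26.1, 85 reads against 22774), ZFAS1 17.6 times (15.1 to 20.6), SNHG15 11.6 times (7.32 to 19.6), and SNHG32 was at the floor of 1 read against 847 (66.0 times lower, 11.8 to 2608). Unfolded protein and integrated stress response genes had a median of -0.86 (percentile 0.06) with 17 of 35 lower and 0 higher: beside NUPR1, the stress transcription factor ATF3 was 11.1 times lower (8.69 to 14.3), HERPUD1, of endoplasmic reticulum protein quality control, 8.89 times (6.93 to 11.6) and the pseudokinase TRIB3 9.81 times (6.27 to 16.3). Nuclear-encoded oxidative phosphorylation genes had a median of -0.73 (percentile 0), with 23 of 74 lower and 2 higher. The complex I subunits NDUFS6, NDUFC2 and NDUFV2 were 7.10, 5.27 and 4.84 times lower. Cytosolic ribosomal protein genes had a median of -0.66, just inside the range of random lists (percentile 2.995, and below it under 6 of 11 alternatives), with 26 of 78 lower and 1 higher. RPS18 was 6.97 times lower (6.35 to 7.68) and RPSA 6.56 times (5.62 to 7.70), while RPS14 stood at 2.84 times WT (2.65 to 3.05). Removing a trend on transcript length, base composition and expression moved the ribosomal protein median to 0.082.

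The other lists lay inside the range of random lists in DGCR8-KO. Genes of the Microprocessor and microRNA pathway had a median of 0.15 (percentile 94.1, 4 of 30 higher, 2 lower), with the silencing factor TNRC6A at 4.56 times (3.94 to 5.27) and TARBP2, a partner of DICER1, 3.68 times lower (1.85 to 8.59). The TGF-beta response and extracellular matrix list had a median of 0.36 (percentile 96.8, 5 of 30 higher, 1 lower), with the fibrillin gene FBN2 at 8.25 times and ACTA2 6.20 times lower. Genes of E2F and DNA replication had a median of -0.30 (percentile 10.7, 2 of 45 higher, 8 lower), and p53 targets one of -0.39 (percentile 2.945, 1 of 25 higher, 5 lower), among them GADD45A, 4.83 times lower (3.66 to 6.5). The p53 median was below 0 under all 11 alternatives and below the range of random lists under 6 of them (percentiles 0.19 to 3.145). Medians of heat shock (0.00, 3 of 21 higher, 3 lower), immediate early (-0.01, 1 of 15 higher, 2 lower) and neuronal genes (-0.07, 1 of 17 higher, 4 lower) were near 0, although HSPA1B stood at 4.05 times WT, HSPA4 was 3.94 times lower and CRMP1 was at the floor of 1 read. Interferon genes had a median of -0.13 (2 of 17 higher, 1 lower) whose sign differed under 6 of 11 alternatives, with 0.72 (percentile 99.55) for the 8 members among the 5000 genes of highest mean and 0.43 (percentile 99.84) for 40 members with no filter on low values.

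**Figure D3:**
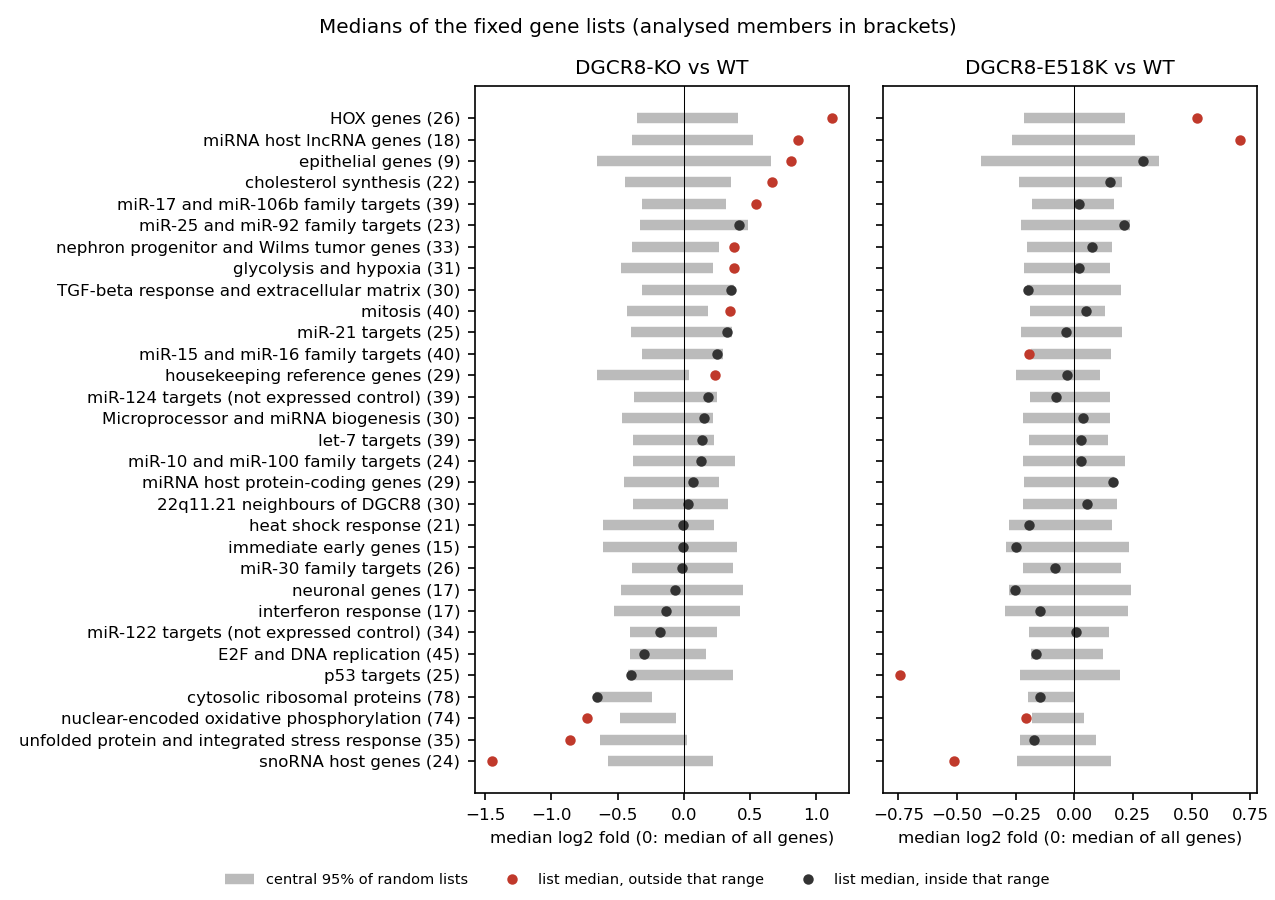
Median log2 fold of each of 31 gene lists in DGCR8-KO vs WT (left) and DGCR8-E518K vs WT (right), relative to the median of all analysed genes, with 1 library per group. Grey bars span the central 95% of 10000 random lists matched on expression; HOX genes (1.12) and small nucleolar RNA hosts (-1.45) are the extremes in DGCR8-KO, and on the uncentred GAPDH scale the nephron, mitosis, glycolysis and housekeeping medians turn negative there.

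The comparison of DGCR8-E518K with WT asks the same of the cells labelled with the substitution. MIR193BHG (chromosome 16, 14301389 to 14331067) was furthest above WT, at 34.9 times (20.8 to 60.9, 63 reads against 20). OVOL2, a transcription factor of epithelial differentiation, had 35 reads against the floor of 1 read in WT (387 times, 65.1 to 15733). CITED1 (chromosome X, 72301638 to 72307187), a transcriptional coregulator active in nephron progenitors, stood at 4.43 times WT (4.15 to 4.72, 1329 reads against 3321) and DGCR8 at 5.32 times. Furthest below WT were the small nucleolar RNA host SNHG32 and the collagen gene COL2A1, both at the floor of 1 read in DGCR8-E518K against 847 and 619 reads, which is 76.5 times (13.7 to 3026) and 55.9 times lower (10 to 2212). CD9, a membrane tetraspanin, was 10.9 times lower (7.30 to 17).

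The 10 highest also held the myosin light chain kinase gene MYLK (9.31 times, 5.84 to 14.7), the sarcomere gene MYOM1 (8.46, 5.43 to 13.1), MIR1244-2 (4.10), and the microRNA hosts MIRLET7BHG (8.30, 5.12 to 13.3), MIR22HG (7.64, 4.59 to 12.6) and MIR181A1HG (6.58, 4.43 to 9.69). A related copy, MIR1244-1, is annotated within an exon of PTMA, so reads of MIR1244-2 could be shared with copies of that gene. The 10 lowest also held MAP7D2 (25.8 times lower, 7.12 to 214), S100P (12), PTCHD4 at the floor of 1 read (35.3), the smooth muscle actin gene ACTA2 (8.47, 5.27 to 14.6), the tubulin gene TUBA1A (6.16), CALCB (6.78) and HNRNPH3 (5.4, 4.74 to 6.17); TUBA1A has close paralogs. Of the 10000 genes, 154 were at least 2-fold higher and 332 lower, with 8 and 23 past 4-fold. Unchanged libraries simulated with counting error alone put 2 genes past 2-fold. Spread between cultures, clones or preparations is absent from that simulation, and with 1 library per group it has no measure. The SD of the log2 folds was 0.50, against 0.88 in DGCR8-KO vs WT. The median on the GAPDH scale was 0.19, and the split turned over with the scale: 387 genes were higher and 169 lower without centring (69.6% higher against 31.7%), and 248 and 195 with each library scaled to its total (56.0%).

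The listed host long noncoding genes were the highest list in DGCR8-E518K, with a median log2 fold of 0.71 (percentile 100), 7 of 18 at least 2-fold higher and 0 lower, led by MIR193BHG, MIRLET7BHG, MIR22HG and MIR181A1HG. HOX genes had a median of 0.52 (percentile 100), with 2 of 26 at least 2-fold higher, HOXB6 (4.05 times, 3.23 to 5.06) and HOXA7 (2.53, 1.95 to 3.25), and 1 lower. Both medians stayed above 0 on every scale tried. The listed protein-coding hosts had a median of 0.17 (percentile 97.3) with 0 of 29 past 2-fold either way. Over all annotated hosts, the 27 long noncoding genes had a median of 0.39 (percentile 99.9, 7 higher, 0 lower), which came from listed members, since the 12 others had -0.02 (0 past 2-fold). The 622 protein-coding genes, DGCR8 among them, had -0.02 (percentile 24.4, 10 higher, 13 lower). Targets of miR-17 and miR-106b had a median of 0.02 (percentile 58.9, 1 of 39 higher, 3 lower), with the cell-cycle inhibitor CDKN1A 3.03 times lower (2.47 to 3.75) and the ubiquitin ligase gene MYLIP at 2.77 times (1.65 to 4.46). Targets of miR-15 and miR-16 were slightly lower as a group, with a median of -0.20 (percentile 1.74) and 2 of 40 at least 2-fold lower, JUN (2.56 times lower, 2.37 to 2.78) and BCL2 (2.99, 1.61 to 6.29); this position was lost among the 5000 genes of highest mean and at equal depth, and the median on the uncentred GAPDH scale was -0.00.

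Targets of p53 were the lowest list in DGCR8-E518K, with a median log2 fold of -0.74 (percentile 0), 8 of 25 at least 2-fold lower and 0 higher. Beside CDKN1A, the antioxidant sestrin gene SESN1 was 3.70 times lower (2.05 to 7.47), the ribonucleotide reductase subunit RRM2B 3.64 times (1.90 to 8.03) and GDF15 2.99 times (2.35 to 3.86). The position of this list held under each of 11 alternatives, among them the uncentred scale and the trimmed mean, which cannot move it. Small nucleolar RNA hosts had a median of -0.51 (percentile 0), with 8 of 24 lower and 0 higher, including ZFAS1 (3.67, 3.44 to 3.93), SNHG15 (3.41, 2.69 to 4.38) and GAS5 (3.02, 2.80 to 3.26). Oxidative phosphorylation genes had a median of -0.21 (percentile 0.73, 5 of 74 lower, 0 higher), among them NDUFC2 (3.39 times lower) and the ATP synthase subunit ATP5PD (2.83); the position was lost when the trend on length, composition and expression was removed, and the median on the uncentred GAPDH scale was -0.01.

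Stress response genes stood inside the range of random lists in DGCR8-E518K, with a median of -0.17 (percentile 11.155, 1 of 35 lower), the 1 being ATF3, 3.15 times lower (2.79 to 3.56). So did ribosomal protein genes (-0.15, percentile 21.7, 1 of 78 higher, 2 lower), mitosis genes (0.05, 0 of 40 past 2-fold) and cholesterol genes (0.15, 1 of 22 higher, 1 lower), where TM7SF2 stood at 3.18 times WT. Nephron progenitor and Wilms tumor genes had a median of 0.08 (percentile 82.8, 2 of 33 higher, 2 lower), and their members spread widely: CITED1 and the tumor suppressor gene AMER1 (2.56 times, 1.84 to 3.5) stood above WT, and COL2A1 and the kidney transcription factor gene WT1 (3.91 times lower, 2.04 to 8.60) below it. Glycolysis genes (0.02) included PFKFB4 at 5.71 times and HK2, which makes the first intermediate of glycolysis, 3.89 times lower (2.85 to 5.44). Lists for TGF-beta (-0.20, percentile 2.83), E2F (-0.17, percentile 4.345), neuronal (-0.25), interferon (-0.15), heat shock (-0.20), immediate early (-0.25), epithelial (0.29) and housekeeping genes (-0.03), and for the Microprocessor pathway (0.04), were inside too. The remaining target lists were also inside, with medians of 0.21 for miR-25 and miR-92, 0.03 for let-7, 0.03 for miR-10 and miR-100, -0.03 for miR-21, -0.08 for miR-30, 0.01 for miR-122 and -0.08 for miR-124.

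Of the 19 ranked seed families, 2 lay in the top 5% of words in DGCR8-E518K vs WT, where chance gives 0.95. The miR-25/32/92 site had a mean log2 fold of 0.10, exceeded by 0.875% of words, and the miR-18 site one of 0.09, exceeded by 0.994%. The miR-17 family site had a mean of -0.01 and was exceeded by 76.7% of words. Control families and families that bypass Microprocessor gave 0 of 8 and 0 of 2. With 7-base sites 1 family was in the top 5%, and with 6-base sites 0.

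DGCR8-E518K was also set directly against DGCR8-KO, to ask where the cells under these labels differ. NUPR1 stood highest, with 248 reads against the floor of 1 read (214 times, 38.1 to 8497), followed by GYPC, the glycophorin C gene, at 11.6 times (8.69 to 15.7), GDF15 with 69 reads against the floor of 1 read (59.6 times, 10.4 to 2388), INHBE at 12.4 times (7.45 to 22) and BEX5 at 25.1 times (8.29 to 124). Lowest were GPC5, 19.7 times lower (11.3 to 37.5), the transcriptional repressor gene BHLHE41 at the floor of 1 read (66.0, 11.4 to 2651), the matrix glycoprotein gene TNC (23.5, 7.68 to 117), PRTG (11.6, 7.25 to 19.8) and CTSA (10.5, 6.55 to 17.9). Differences of at least 2-fold numbered 980 higher and 933 lower, and the counting intervals of 980 and 920 of them excluded 1. Unchanged libraries simulated with counting error alone, and so with no spread between cultures, clones or preparations, put 35 genes past 2-fold. Without centring, where the median log2 fold was 0.61, 2995 genes were higher and 191 lower (94.0% higher against 51.2%).

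Stress response genes were higher in DGCR8-E518K than in DGCR8-KO, with a median log2 fold of 0.91 (percentile 100), 17 of 35 at least 2-fold higher and 0 lower, among them TRIB3 (9.28 times, 5.79 to 15.7), XBP1, a transcription factor of the unfolded protein response (4.71, 4.0 to 5.56) and HERPUD1 (4.70, 3.57 to 6.26). Small nucleolar RNA hosts had a median of 0.78 (percentile 99.99, 11 of 24 higher, 0 lower), with GAS5 at 6.93 times (5.53 to 8.79). Oxidative phosphorylation genes (0.42, percentile 99.4, 5 of 74 higher) and ribosomal protein genes (0.55, percentile 99.5, 20 of 78 higher) were above the range too, but both positions were lost when the trend on length, composition and expression was removed, and the ribosomal median then turned to -0.04. Targets of miR-17 and miR-106b were lower, with a median of -0.70 (percentile 0), 14 of 39 at least 2-fold lower and 0 higher: ENPP5 was 12.3 times lower (4.94 to 39.3), CROT 6.94 times (2.67 to 22.9) and TNFRSF21, a death receptor, 3.56 times (1.87 to 7.26). The miR-17 family site had a mean of -0.26, exceeded by 99.97% of words. It was 1 of 6 dependent families among the lowest 5% of words, with miR-18 (-0.17), miR-148 (-0.14), miR-19 (-0.13), miR-221 (-0.10) and miR-25/32/92 (-0.10). Of the 19 ranked, 0 were in the top 5%, and of 8 control families 0 were in the lowest 5%.

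HOX genes (median -0.75, percentile 0, 8 of 26 lower, 0 higher) and cholesterol genes (-0.69, percentile 0, 9 of 22 lower, 1 higher) were lower in DGCR8-E518K than in DGCR8-KO on every scale tried; HOXB5 was 9.11 times lower (5.30 to 16.8) and INSIG1 9.97 times (6.63 to 15.6). A further 10 lists had medians below the range of random lists that turned positive on the uncentred GAPDH scale: targets of miR-25 and miR-92 (-0.49, 5 of 23 lower, 2 higher), of miR-15 and miR-16 (-0.48, 10 of 40 lower, 2 higher) and of miR-21 (-0.37, 3 of 25 lower, 1 higher), and the lists for TGF-beta and matrix (-0.52, 9 of 30 lower), interferon (-0.48, 3 of 17 lower, 1 higher), immediate early (-0.56, 4 of 15 lower, 2 higher), nephron and Wilms tumor (-0.38, 4 of 33 lower), mitosis (-0.26, 4 of 40 lower, 3 higher), housekeeping (-0.26, 3 of 29 lower, 2 higher) and glycolysis genes (-0.23, 3 of 31 lower, 1 higher). Examples are RHOB, a small GTPase gene among the miR-21 targets (6.02 times lower, 4.94 to 7.40), KIF23 (4.10, 2.53 to 6.92), MAN2A1 among the miR-25 targets (4.53, 2.87 to 7.42) and B2M (3.66, 3.20 to 4.19). The positions of the miR-21, nephron and TGF-beta lists held under all 11 alternatives, and that of glycolysis under only 3. These tallies include the uncentred scale and the trimmed mean, which cannot move a position. Among the 5000 genes of highest mean the miR-25 and miR-92, miR-15 and miR-16 (percentile 11.645) and mitosis positions were lost. Without matching on expression the mitosis and housekeeping positions were lost, with the trend on length, composition and expression removed those of miR-25 and miR-92 and of interferon, and with list means that of immediate early genes. The control target lists were inside the range, with medians of 0.33 for miR-122 (percentile 96.38) and -0.22 for miR-124 (percentile 3.045, 7 of 39 lower, 4 higher). They lay outside, on the same sides, under 2 and 4 of 11 alternatives. The listed host long noncoding genes had a median of 0.12 (percentile 80.3, 1 of 18 higher, 2 lower), the latter being MIR222HG (8.80 times lower, 3.46 to 28.6) and MIR17HG (4.22, 2.87 to 6.36).

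Both comparisons with WT were then set side by side. Of the genes at least 2-fold higher, 83 were shared, and of those at least 2-fold lower, 168, where independent lists of these sizes would share 16.6 and 40.5. Over the alternatives these overlaps ranged from 17 to 224 and from 85 to 497. Unchanged libraries with the same WT shared 0 and 0 from counting error alone. With noise as wide as the folds of DGCR8-E518K (SD 0.35 log2 per library) they shared 23.7 and 31.4. With that noise their lists were shorter (195 and 176 genes higher, 266 and 218 lower), and independent lists of those sizes would share 3.42 and 5.78. As a ratio to independent lists, the excess of these noisy unchanged libraries was no smaller than the observed one. Shorter lists allow larger ratios, however, and the noise was the same in every library. The observed folds of DGCR8-KO vs WT were wider (SD 0.88, against 0.50 for DGCR8-E518K vs WT). The ratio therefore cannot tell whether noise gives as much overlap. The shared higher genes held 7 of the 18 listed host long noncoding genes (MIR17HG, MIR22HG, MIRLET7BHG, MIR181A1HG, MIR193BHG, DLEU2 and FTX), CITED1, HOXA7 and HOXB6. Among the shared lower genes were 8 of 24 small nucleolar RNA hosts (SNHG5, SNHG12, SNHG15, SNHG19, SNHG29, SNHG32, GAS5 and ZFAS1), 4 oxidative phosphorylation genes (NDUFC2, SDHC, ATP5PB and ATP5PD) and the p53 targets GADD45A, AEN and GDF15. Members of these shared sets that no part of the naming rule covers, such as FTX and AEN, were listed after their values were seen. Across genes, which are not independent replicates, the log2 folds of the comparisons had Pearson's r of 0.46 and Spearman's rho of 0.42. Simulated unchanged libraries gave r of 0.06, or 0.41 with the added noise. That noise was the same in every library, whereas the observed folds of DGCR8-KO vs WT were wider. The r of 0.41 and the observed 0.46 are therefore not like measures. The covariance was 0.204, against 0.00289 and 0.101 in those simulations. Both comparisons use the 1 WT library. With its reads split at random into a part for each comparison, a step chosen after the data had been seen, r was 0.45 and the overlaps 81.3 and 162 (means of 20 splits), so shared counting error accounts for little of the overlap. The WT culture itself could not be split, and part or all of the excess may come from it.

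**Figure D4:**
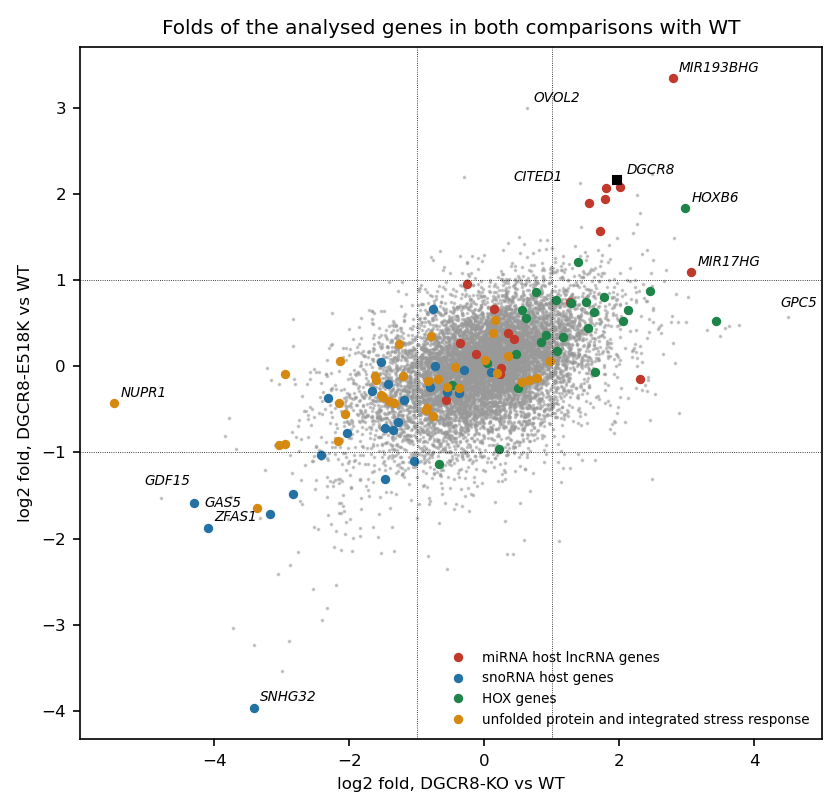
Log2 fold in DGCR8-E518K vs WT (vertical axis) against that in DGCR8-KO vs WT (horizontal axis) for the 10000 analysed genes, relative to the median gene and with 1 library per group. Dotted lines mark 2-fold, colours mark 4 gene lists and the black square DGCR8; 7 listed host long noncoding genes lie past 2-fold in the upper right and 8 small nucleolar RNA hosts in the lower left, and both axes share the WT library.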

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

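Thinning to the DGCR8-KO depth, removal of the transcript trend, weighting of words, splitting of the WT reads and host lists from the annotation were chosen only after the data had been seen. Of 130 counts, correlations and DGCR8 ratios recomputed under alternatives, 87 stayed close to the reported value and 43 moved. Most are counts, which have no sign. Pearson's r across genes ranged from 0.43 to 0.56 over the alternatives, and the number of lists outside the random range in DGCR8-KO vs WT from 11 to 18. Scale moved the split between higher and lower genes most visibly: 14.5% of 2-fold genes were higher in DGCR8-KO than in WT on the deposited GAPDH scale and 63.9% with library totals, against 46.9% as reported. For DGCR8-E518K vs WT the shares were 69.6% and 56.0% against 31.7%. Unless stated otherwise the cause was not tested. Depth limits the edited libraries, where 6493 and 5588 genes stood at the floor of 1 read, and a single library per group leaves clone, culture and library preparation without any measure of spread. No paired analysis was possible because each group had 1 library with no partner. Leaving out a replicate was not possible for the same reason.

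On the deposited GAPDH scale without centring, 414 genes were higher and 2444 lower in DGCR8-KO vs WT, 387 and 169 in DGCR8-E518K vs WT, and 2995 and 191 in DGCR8-E518K vs DGCR8-KO. This follows from the shifts of -0.42, 0.19 and 0.61 in the median gene, which also turned the list medians of nephron, mitosis, glycolysis and housekeeping genes in DGCR8-KO vs WT to -0.04, -0.07, -0.05 and -0.19. With library totals, 1636 genes were higher in DGCR8-KO vs WT, and 248 were higher and 195 lower in DGCR8-E518K vs WT. The log2 ratio of DGCR8 in DGCR8-KO vs WT was 1.74 on the deposited scale, 2.46 with library totals and 2.17 after centring. With a pseudocount of 1/100 of the median level, 307 genes were higher in DGCR8-E518K vs WT and 160 were higher in both edited libraries. With 1/2 of the median level, counts of higher and lower genes were 349 and 684, 30 and 112, and 423 and 277 in the same order of comparisons, and the overlaps 17 higher and 86 lower. Among the 5000 genes of highest mean, which leaves fewer genes to count, they were 456 and 553, 42 and 120, and 358 and 305, with overlaps of 24 and 85. With no filter on low values, 2824 genes were lower in DGCR8-KO vs WT, 568 higher and 1035 lower in DGCR8-E518K vs WT, and 2601 and 1560 in DGCR8-E518K vs DGCR8-KO, with overlaps of 168 and 497. Lists outside the random range in DGCR8-E518K vs WT then numbered 10, as they did with list means (10). With sites of 7 bases 3 seed families were in the top 5% of words in DGCR8-KO vs WT, 2 of them among the 5 reported, and 1 in DGCR8-E518K vs WT, where sites of 6 bases gave 0. At the DGCR8-KO depth, 384 genes were higher in DGCR8-E518K vs WT and 224 higher in both.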

Other observations

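The comparison of exon with intron hosts within the listed host genes, the use of all annotated hosts and that of seed words with words of the same bases were chosen only after the result was seen, and the gene sets linked to ATF4, the chaperone set, the tRNA synthetases and the 5' TOP set were defined after the list medians had been seen. The stress list was uneven in DGCR8-KO. Its 18 members linked to ATF4, the transcription factor of the integrated stress response, had a median log2 fold of -1.57 against WT (percentile 0; 12 at least 2-fold lower, 0 higher), while its 17 chaperone and protein quality control members had -0.43 (percentile 20.6; 5 lower, 0 higher). PPP1R15A, which restores translation after stress, stood at -2.95, the glutathione-degrading CHAC1 at -2.15 and asparagine synthetase ASNS at -1.61, whereas ATF4 itself stood at 0.16. Among the chaperone set, XBP1 stood at -2.13 and HSPA5 at -1.20, but CALR at 0.79 and HYOU1 at 0.66. Outside the list, 16 amino acid genes linked to ATF4 had a median of -1.01 (percentile 0.25; 8 lower, 1 higher), with the transporter SLC1A4 at -2.83 and the transsulfuration enzymes CBS and CTH at -2.58 and -2.29; SLC7A5, at 1.25, went the other way. In DGCR8-E518K the 18 members linked to ATF4 had a median of -0.38 (percentile 0.42; 1 lower) and the amino acid genes -0.07 (percentile 48.3; 1 lower). Against DGCR8-KO, DGCR8-E518K had 12 of these 18 members higher, with a median of 1.37.

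GPC5, the gene furthest above WT in DGCR8-KO, starts at 91398607 on the plus strand of chromosome 13, downstream of MIR17HG, which ends at 91354579 on the same strand. Both stood highest in DGCR8-KO, with 153 and 85.6 reads per 1000 GAPDH reads. In DGCR8-E518K vs WT, MIR17HG stood at 2.60 times (1.73 to 3.79) and GPC5 at 1.92 times with an interval that included 1 (0.976 to 3.48). The pair was singled out after its values were seen, and read-through between the genes was not tested. Other 5' TOP transcripts, which share a translational control element with ribosomal protein genes, had a median of -0.28 over 21 members in DGCR8-KO (percentile 70.3; 1 higher, 4 lower).

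The host long noncoding genes listed in advance were higher in both edited libraries, whereas the 12 annotated hosts outside the list were not, with medians of -0.24 and -0.02, so the pattern is one of the listed hosts. With all libraries at the DGCR8-KO depth the lower of the list's 2 medians was 0.88, after removal of the transcript trend it was 0.76, and among lists of 216 other long noncoding genes the list stood at percentile 100 in both comparisons, which argues against depth, that trend and a general rise of noncoding transcripts as the whole cause. Uncut hairpins may stabilise these transcripts when Microprocessor is impaired, but this stays open. Across 651 genes with an annotated microRNA, hosts with it in an exon differed from intron hosts by -0.040 in DGCR8-KO and 0.031 in DGCR8-E518K; the first was set in advance to count against the idea, but only 2.46% of those genes are in the list. Long noncoding hosts alone showed no exon excess, with medians of 0.22 for 10 exon and 0.25 for 17 intron hosts in DGCR8-KO, and 0.37 and 0.41 in DGCR8-E518K. Only 4 of those 10 exon hosts are in the list, and hosts outside it were not higher, so this comparison does not decide either. Within the list, 4 exon hosts had medians of 1.90 and 1.52 in DGCR8-KO and DGCR8-E518K against 0.76 and 0.71 for 12 intron hosts, and the smaller difference, 0.81, stood at percentile 83.25 of shuffled labels, too few genes to decide.

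Lists lower in DGCR8-KO behaved differently once the trend on transcript length, base composition and expression was removed. Stress genes stayed at -0.73 and small nucleolar RNA hosts at -1.06, which argues against that trend as their whole cause, and stress genes at equal depth stood at -1.04, which argues against depth. Ribosomal protein genes moved to 0.082, so that the trend is a candidate explanation for them, and oxidative phosphorylation genes moved from -0.73 to -0.27, between the bounds set in advance. That list stayed below the range of random lists (percentile 0.84), so the trend did not end its position, and how much of the fall it accounts for stays open. Lower ATF4-linked transcription in the DGCR8-KO culture is a candidate explanation for the stress genes: tRNA synthetases linked to ATF4 had a median of -1.0 (percentile 1.9; 6 of 12 lower), against -0.38 for 8 others (1 higher, 2 lower), a difference of -0.63. Whether the edit, the clone or the state of the culture at harvest lies behind it was not tested, since each group had 1 library.

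Seed words of Microprocessor-dependent families were among the highest words in DGCR8-KO, with 5 of 19 in the top 5% against 0 of 8 control families, a gap of 26.3 percentage points that lies between the bounds set in advance. Words made of the same bases in another order argue against base composition of 3' UTRs as the whole cause: 5 of the 19 families were in the top 5% of the words of their own bases, where chance gives 0.95, and none of 327 such words exceeded the miR-17 site. Removal of the 3' UTR trend on composition, length and level left that site at 0.25, against 0.35 without it. Loss of repression by these microRNAs may explain the pattern, but with 1 library per group the clone was not tested apart from the edit. The ranks of miR-17 and miR-18 held for 8-base sites and not for shorter ones. Genes with a shorter site include those with the 8-base site, so that loss of rank does not decide for or against the idea.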
